A study of Mus musculus with 30 samples.

How the data were processed

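Left ventricle samples of mice, 30 in 4 groups of 5 or 10, were sequenced as strand-specific mRNA libraries with paired 100-base reads, from 1.3 ug of total RNA each. Per the labels, the authors used Trim Galore 0.6.4, TopHat, Bowtie2 2.2.9 and edgeR 3.17 with the genome build mm10. The counting program and the strand setting are not stated. The authors deposited 2 files per library, one with raw counts per gene and one with CPM (counts per 1e6 counts of the library). The deposited CPM were checked and equal the counts divided by the library total, with no scaling factors. Each file lists 24467 Entrez gene IDs. Symbols came from RefSeq for 24437 of them and from GENCODE for 7, and 23 stayed without a symbol. The files list 0 mitochondrially encoded genes. Library totals ran from 9231678 to 13093351 counts, so 3 counts correspond to about 0.3 CPM.

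The deposited counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and sva 3.50.0. Genes were kept by filterByExpr (minimum count 10), which left 13588, and libraries were scaled by TMM factors. One quasi-likelihood model of edgeR (robust) with the 4 groups as terms was fitted to all 30 libraries. It estimates 1 spread per gene over all groups, so a standard error also reflects groups outside the comparison. Tests were two-sided F tests, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. The 5 comparisons were TAC against Sham within each genotype, TG against NTG within each surgery, and the interaction. Log2 fold changes carry standard errors, computed as the absolute log2 fold change divided by the square root of its F statistic. Group values are means and SDs of TMM-scaled CPM. Counts of genes adjusted over the list alone used the p of the members of a list only. Log2 CPM for the list tests used a prior count of 2.

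The comparisons, the gene lists and the rule for named genes were fixed before the data were examined. The rule took, for each comparison, the 8 largest rises and 8 largest falls among called genes with a mean CPM of at least 2, the 4 members with the smallest p of each list, and 10 named hypertrophy and matrix genes. The text names a part of these by list membership or rank. Of the lists, 33 had enough tested members. They were tested in each comparison by camera with a preset correlation of 0.01, by camera with an estimated correlation and by fry, over 165 tests with 1 adjustment each. Fry asks whether the genes of a list move on balance in 1 direction.

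The alternatives were other normalizations (RLE and upper-quartile factors), no filter and a strict filter (CPM of at least 1 in at least 5 libraries), DESeq2, limma voom with sample quality weights, limma-trend on the deposited CPM, a fit of the groups of each comparison alone, the replicate number as a block, the number in the sample name as a 2-level term (under 100, or 100 and more), 1 surrogate variable, a test against a fold of 1.2, and leaving out each of the 30 libraries in turn. Replicate numbers do not pair the samples: over 25 pairs with the same number the median correlation of deviations from the group means was 0.05, and 2 of 15 samples matched best with their own number. The highest of these correlations was 0.55, between replicate 1 of NTG TAC and replicate 1 of TG TAC. Every library carried counts of Y-linked genes, so a sex term was not fitted. No 2 libraries of the same group were the same beyond counting error, with a lowest chi-square per degree of freedom of 2.85 over 110 pairs. Pairs of libraries from different groups were not compared in this way.

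The model was tested on simulated counts with the means, dispersions and library sizes of the data, 13588 genes and 200 changed genes. Of the genes changed 1.5-fold, it called 57 of 67 for TAC in NTG hearts, 55 of 67 for TAC in TG hearts, 54 of 67 for genotype after Sham, 62 of 67 for genotype after TAC and 40 of 67 for the interaction, with 4 to 12 false calls. The simulation gave each gene the same dispersion in every group and drew genes independently. These values therefore do not test the model where groups differ in spread, as the NTG TAC and TG TAC libraries did, or where genes move together. Random splits of the libraries were drawn 100 times for each count of genes. Permutation tests of correlations and spreads used 100000 resamples, or all arrangements with fewer than 10 values.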

Results

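RNA of 30 mouse left ventricle samples was measured by strand-specific mRNA sequencing. The mice were either non-transgenic (NTG) or carried a transgene for the human relaxin receptor, hRXFP1 (TG), and had 8 weeks of transverse aortic constriction (TAC), a surgical narrowing of the aorta that loads the left ventricle, or a Sham operation. The groups held 5 NTG Sham, 10 NTG TAC, 5 TG Sham and 10 TG TAC hearts, with 1 library each. Library totals ran from 9231678 to 13093351 counts, and 13588 genes had enough counts to be tested. The first component of a principal component analysis held 37.4% of the variance of log2 CPM (counts per 1e6 counts of the library). The mouse gene Rxfp1 had 0 to 14 counts in each library, with the 14 in TG TAC replicate 2. Its mean CPM was 0.122 ± 0.0835 (SD, n = 5) in NTG Sham and 0.192 ± 0.147 (SD, n = 10) in NTG TAC hearts. In TG hearts it was 0.216 ± 0.232 (SD, n = 5) after Sham and 0.363 ± 0.423 (SD, n = 10) after TAC. These counts are assigned to the mouse gene. Whether reads of the human transgene were counted on it was not tested, so they do not check the transgene.

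The number in each sample's deposited name, whose meaning the labels do not give, was 100 or more in 4 of 5 NTG Sham, 5 of 5 TG Sham, 3 of 10 NTG TAC and 1 of 10 TG TAC libraries. If these numbers follow batches, TAC and batch overlap in large part. The TG TAC library with a number of 100 or more, replicate 1, lay at 0.30 on a scale where 0 is the mean of the TG Sham and 1 the mean of the TG TAC libraries, with the placed library left out of both means. Placed in the same way, the 5 TG Sham libraries lay between 0.12 and 0.32, so Sham libraries lie above 0 on this scale. On the matching NTG scale, NTG TAC libraries ran from 0.12 (replicate 1) to 1.98 (replicate 10) and NTG Sham libraries from 0.10 to 0.29. NTG TAC replicates 1 and 7 (0.12 and 0.28) thus lay within the Sham range. Its upper end is NTG Sham replicate 5, and the other NTG Sham libraries lay at 0.10 to 0.12, below NTG TAC replicate 7. NTG TAC replicates 2 and 3, with numbers of 100 or more, do not follow the numbers, at 1.78 and 1.57. NTG TAC replicate 1, with a number of 107, lay near the Sham hearts as its number would predict. NTG Sham replicate 5, with a number under 100, lay at 0.29, the highest of its group, but it also held lymphocyte transcripts. These places do not decide whether the numbers follow batches.

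The first comparison asks how non-transgenic hearts responded to pressure overload. Genes of the cardiac hypertrophy programme, which are raised in stressed heart muscle, rose together. Acta1, the skeletal muscle form of alpha-actin (gene ID 11459, chromosome 8), rose from 789 ± 309 CPM (SD, n = 5) to 7744 ± 4141 CPM (SD, n = 10), a log2 fold change of 3.30 ± 0.52 (SE, adjusted p = 0.000933 by the edgeR quasi-likelihood test), and was above the Sham mean in 10 of 10 TAC hearts. Nppa, which encodes atrial natriuretic peptide (gene ID 230899, chromosome 4), rose by a log2 fold change of 3.87 ± 0.75 (adjusted p = 0.00238). Myh7, the slow beta-myosin heavy chain, rose by 1.38 ± 0.34 (adjusted p = 0.00944), Nppb, which encodes brain natriuretic peptide, by 1.63 ± 0.46 (adjusted p = 0.0173) and Ankrd1, a stress-responsive protein of the sarcomere and nucleus, by 1.84 ± 0.34 (adjusted p = 0.00173). Myh6, the fast alpha-myosin heavy chain, had a log2 fold change of -0.39 ± 0.14 and did not pass (adjusted p = 0.0516). It passed without NTG TAC replicate 1, 4, 6, 7, 9 or 10 or TG TAC replicate 1 (adjusted p from 0.0194 to 0.0493), and with RLE factors, DESeq2, voom, limma-trend and the replicate block (0.0494, 0.0377, 0.0169, 0.0373 and 0.0374).

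Of the 17 tested members of the hypertrophy list, 17 rose, and 17 did so adjusted over the list alone. Of the 34 tested members of the extracellular matrix list, 30 rose and 0 fell, with 33 rising when adjusted over the list alone. Postn, which encodes periostin, a matrix protein of activated fibroblasts, rose by a log2 fold change of 3.36 ± 0.70 (adjusted p = 0.00381), Ltbp2, a microfibril-associated protein, by 4.96 ± 0.96 (adjusted p = 0.00246), Cilp by 3.89 ± 0.75 (adjusted p = 0.00238) and Col1a1, a chain of type I collagen, by 1.38 ± 0.39 (adjusted p = 0.0172). In the list of the transforming growth factor beta pathway, 11 of 20 members rose and 3 fell (13 and 3 adjusted over the list alone), with Tgfb3 at 0.94 ± 0.22 (adjusted p = 0.00662). Of 23 macrophage markers, 9 rose (18 adjusted over the list alone), with Cd14 at 0.91 ± 0.21 (adjusted p = 0.00576) and Lgals3, which encodes galectin-3, at 2.72 ± 0.80 (adjusted p = 0.0223). Lgals3 lost the call without NTG Sham replicate 2 (adjusted p = 0.0555). The preset camera test gave these lists adjusted p = 1.68e-12, 1.04e-15, 0.000916 and 5.71e-06, and with an estimated correlation adjusted p = 0.507, 0.507, 0.507 and 0.549.

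Genes of mitochondrial fuel oxidation fell, in 4 lists. In the oxidative phosphorylation list, 39 of 50 members fell and 0 rose (47 and 0 adjusted over the list alone), including Cox7a1, a subunit of complex IV, at -0.62 ± 0.16 (adjusted p = 0.00985) and Sdha, a subunit of complex II, at -0.40 ± 0.11 (adjusted p = 0.0117). In the fatty acid oxidation list, 19 of 31 members fell (22 adjusted over the list alone), such as Acot1, an acyl-CoA thioesterase, at -1.37 ± 0.34 (adjusted p = 0.0098). In the tricarboxylic acid cycle list, 11 of 19 members fell (14 adjusted over the list alone), such as Cs, which encodes citrate synthase, at -0.38 ± 0.09 (adjusted p = 0.00854). In the list of branched-chain amino acid and ketone metabolism, 12 of 22 members fell and 1 rose (15 and 1 adjusted over the list alone). The riser was Bdh1, a ketone body enzyme, at 1.196 ± 0.174 (adjusted p = 0.000543). Camera gave these 4 lists adjusted p = 5.18e-18, 5.09e-11, 3.67e-08 and 2.16e-06 with the preset correlation, and with an estimated correlation adjusted p = 0.507, 0.507, 0.534 and 0.549. Of the 23 glycolysis genes, 3 rose and 4 fell (7 and 5 adjusted over the list alone), and the list was not called (adjusted p = 0.408).

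Ion channel genes fell in 11 of 22 cases (13 adjusted over the list alone), such as Kcnj3, a subunit of the atrial acetylcholine-gated potassium channel, at -0.77 ± 0.21 (adjusted p = 0.0131) and Gja1, which encodes connexin 43, at -0.37 ± 0.09 (adjusted p = 0.00825). Calcium-handling genes fell in 6 of 18 cases (8 adjusted over the list alone), such as Ryr2, the calcium release channel of the sarcoplasmic reticulum, at -0.34 ± 0.08 (adjusted p = 0.00825). The calcium pump gene Atp2a2 fell by 0.42 ± 0.15 on the log2 scale with adjusted p = 0.0426, and Pln, its inhibitor, by 0.39 ± 0.12 with adjusted p = 0.0298. Atp2a2 lost the call without any 1 of the NTG Sham replicates or of NTG TAC replicates 2, 3, 5, 6 and 8 (adjusted p from 0.0504 to 0.0896), and Pln without NTG Sham replicate 1, 2, 3 or 4 or NTG TAC replicate 3 (from 0.0507 to 0.069). Camera called both lists (adjusted p = 5.88e-06 and 0.023), with adjusted p = 0.507 and 0.507 with an estimated correlation. Among the largest falls were the T cell genes Cd8b1, Cd8a, Tcf7 and Lck, at log2 fold changes between -3.93 ± 0.91 and -3.17 ± 0.78. These rest on 1 library, NTG Sham replicate 5, without which Cd8b1 was at -0.40, Tcf7 at -0.07, Cd8a at 0.10 and Lck at 0.24, and none of the 4 passed. The next largest fall was in Ccl11, which encodes the chemokine eotaxin, at -2.22 ± 0.38 (adjusted p = 0.000951).

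**Figure D1:**
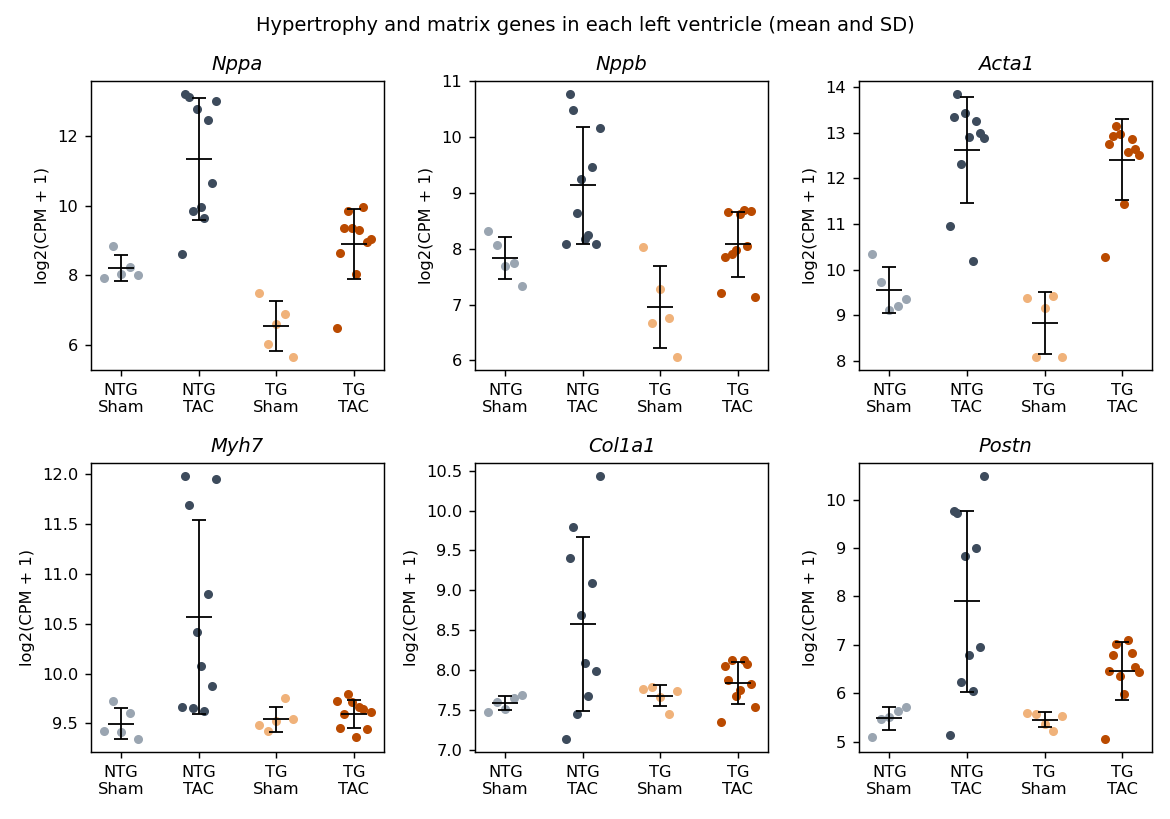
Log2(CPM + 1) of 6 genes in each left ventricle by group (points), with the mean and SD (black). Acta1 lies above the highest NTG Sham heart in most TAC hearts of both genotypes, and the NTG TAC hearts spread widely for Myh7, Col1a1 and Postn.

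In all, 1285 genes rose and 1105 fell with TAC in NTG hearts (n = 5 and 10). A fit of the 15 NTG libraries alone called 132 and 86 genes. In that fit Acta1, Nppa, Ankrd1, Cilp, Bdh1, Ccl11, Cd8b1 and Cd8a passed, and the other called genes named above did not, with adjusted p from 0.0521 (Ltbp2) to 0.183 (Atp2a2). These include Myh7, Nppb, Col1a1 and Postn (adjusted p = 0.099, 0.0901, 0.122 and 0.0663), Cox7a1, Sdha, Acot1 and Cs (0.0959, 0.0978, 0.0786 and 0.0913), and Kcnj3, Gja1, Ryr2 and Pln (0.113, 0.069, 0.0825 and 0.152). Acta1, Nppa, Ankrd1, Cilp, Bdh1 and Ccl11 passed under all alternatives that were run. Leaving out NTG Sham replicate 4 gave 1550 calls in place of 2390, and adding 1 surrogate variable gave 316. With the surrogate variable Myh7 was at 0.35 (adjusted p = 0.314), Nppb at 0.43 (0.559), Col1a1 at 0.14 (0.599) and Postn at 1.11 (0.0527). Nppb and Ltbp2 did not pass with voom (0.0631 and 0.0609), nor Sdha, Atp2a2 and Pln with the number in the sample name as a 2-level term (0.0518, 0.138 and 0.059). Lgals3 was not called with voom, limma-trend or the replicate block, Col1a1 not with limma-trend or the replicate block, and Nppb not with the replicate block.

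The second comparison asks the same of transgenic hearts. Acta1 rose by a log2 fold change of 3.64 ± 0.53 (adjusted p = 0.00092, edgeR), from 494 ± 207 CPM (SD, n = 5) to 6146 ± 2411 CPM (SD, n = 10). Next in size among the rises were Tbx15, a T-box transcription factor, at 2.898 ± 0.522 (adjusted p = 0.00295) and Aqp8, a water channel, at 2.11 ± 0.39 (adjusted p = 0.00373). Ankrd1 rose by 1.59 ± 0.33 (adjusted p = 0.0111) and lost the call without TG Sham replicate 2 (adjusted p = 0.0529). Bdh1 rose by 0.92 ± 0.17 (adjusted p = 0.00398). Among the falls, Phgdh, the entry enzyme of serine synthesis, fell by 1.75 ± 0.35 on the log2 scale (adjusted p = 0.00563), Mthfd2, a mitochondrial folate enzyme, by 1.54 ± 0.26 (adjusted p = 0.0025) and Aldh1l2, another mitochondrial folate enzyme, by 1.26 ± 0.21 (adjusted p = 0.00191). Asns, which encodes asparagine synthetase, fell by 1.16 ± 0.21 (adjusted p = 0.00351).

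Several genes that rose in NTG hearts did not pass in TG hearts. Nppa had a log2 fold change of 2.48 ± 0.69 (adjusted p = 0.0676), Nppb of 1.07 ± 0.45 (adjusted p = 0.25), Myh7 of 0.06 ± 0.32 (adjusted p = 0.957), Col1a1 of 0.18 ± 0.37 (adjusted p = 0.877) and Postn of 1.11 ± 0.63 (adjusted p = 0.441). Nppa passed without TG TAC replicate 1 at 2.61 (adjusted p = 0.034) and without NTG TAC replicate 1 (adjusted p = 0.0398), and with DESeq2, voom, 1 surrogate variable and a fit of the TG libraries alone (adjusted p = 0.00258, 0.00199, 0.00458 and 0.0115). Nppb passed with voom (adjusted p = 0.0231) and with 1 surrogate variable (0.0397). Postn passed with 1 surrogate variable (0.0364) and in a fit of the TG libraries alone (0.026), whereas in the fit of the NTG libraries alone it did not pass in NTG hearts (0.0663). Of the 17 hypertrophy genes, 3 rose (5 adjusted over the list alone), and of the 23 genes of the unfolded protein and integrated stress response, 3 fell (11 adjusted over the list alone). Camera called these lists up and down (adjusted p = 9.42e-09 and 7.4e-11), and both had adjusted p = 0.507 with an estimated correlation. The matrix list had 0 called members of 34 (0 adjusted over the list alone), 33 with a positive value and a median log2 fold change of 0.31, and camera called it up (adjusted p = 2.64e-05, and adjusted p = 0.682 with an estimated correlation). The ion channel list had 2 lower members, Gja5, which encodes connexin 40, at -0.60 ± 0.14 and Cacna1g, a T-type calcium channel, at -0.41 ± 0.10 (2 adjusted over the list alone). Gja5 lost its call without TG Sham replicate 1 (adjusted p = 0.0612) and Cacna1g without TG Sham replicate 2 (0.106), 3 (0.0514) or 5 (0.0569). Camera called that list down (adjusted p = 0.000112, and adjusted p = 0.507 with an estimated correlation).

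In all, 122 genes rose and 72 fell with TAC in TG hearts (n = 5 and 10). With the number in the sample name as a 2-level term, 13 rose and 2 fell, and of the genes above Acta1 still passed while Tbx15, Aqp8, Mthfd2, Phgdh, Asns and Aldh1l2 did not (adjusted p = 0.0603, 0.173, 0.142, 0.136, 0.223 and 0.149), nor did Ankrd1, Bdh1, Gja5 and Cacna1g (0.108, 0.181, 0.252 and 0.407). Their log2 fold changes in this fit were 2.895, 1.61, -1.42, -1.87, -0.91 and -1.03 for the first 6 and 1.77, 0.74, -0.49 and -0.24 for the last 4, so some lost the call with a change as large as before and others with a smaller one. The count of 194 was 93 without TG Sham replicate 2, 124 without replicate 3, 109 without replicate 5 and 296 without TG TAC replicate 1, and 954 in a fit of the 15 TG libraries alone.

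The 2 sets of TAC calls shared 86 rising and 39 falling genes, where 11.5 and 5.86 would be shared by chance if the sets were unrelated, and 1 gene was called in opposite directions. Over all 13588 genes the 2 TAC log2 fold changes had Pearson's r = 0.62 and a slope of 0.37. Genes are not independent replicates, and both changes come from separate Sham groups. Both sets of calls use the same spread per gene from 1 fit, which the chance values do not allow for. Of the 2390 genes called in NTG hearts, 2197 had the same sign in TG hearts, and of the 194 called in TG hearts, 183 had the same sign in NTG hearts. In fits of the groups of each comparison alone, over the 13122 genes tested in both, 214 genes were called in NTG and 951 in TG hearts, so which genotype had more calls depends on the fit. The calls of these separate fits shared 91 rising and 40 falling genes, where 5.40 and 2.60 would be shared by chance.

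The third comparison asks what the transgene changes without pressure overload. The 8 largest rises in TG Sham hearts were in Mthfd2, Asns, Phgdh, Chac1, Nav2, Aldh1l2, Slc7a5 and Atf5, the first 4 of them members of the list of the unfolded protein and integrated stress response. Mthfd2 (gene ID 17768, chromosome 6) was at 70.4 ± 9.8 CPM (SD, n = 5) against 2.53 ± 1.29 CPM (SD, n = 5), a log2 fold change of 4.79 ± 0.41 (SE, adjusted p = 1.81e-08, edgeR quasi-likelihood), higher in 5 of 5 hearts. Asns (gene ID 27053, chromosome 6) rose by 3.84 ± 0.31 (adjusted p = 2.93e-09), Phgdh by 3.03 ± 0.48 (adjusted p = 0.000366), Chac1, a glutathione-degrading enzyme, by 2.13 ± 0.38 (adjusted p = 0.002, and 0.139 in a fit of the Sham libraries alone) and Aldh1l2 by 2.10 ± 0.27 (adjusted p = 7.95e-06). Slc7a5, a transporter of large neutral amino acids, rose by 2.10 ± 0.25 (adjusted p = 4.52e-06), and Atf5, a stress-induced transcription factor, by 1.75 ± 0.20 (adjusted p = 4.13e-06).

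Of the 23 tested genes of the unfolded protein and integrated stress response, 11 rose and 0 fell (21 and 0 adjusted over the list alone). Camera gave the list adjusted p = 4.03e-48 with the preset correlation and adjusted p = 0.000566 with an estimated correlation. It was the only one of 165 list tests over the 5 comparisons whose call held with the estimated correlation. Nav2, a neuron navigator protein (gene ID 78286, chromosome 7, 48959063 to 49610090 on GRCm38), was at 479 ± 49.1 CPM (SD, n = 5) in TG Sham and 111 ± 7.63 CPM (SD, n = 5) in NTG Sham hearts, a log2 fold change of 2.11 ± 0.10 (adjusted p = 3.31e-16).

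Fewer genes were lower. Dbh, which encodes dopamine beta-hydroxylase, fell by 1.496 ± 0.321 on the log2 scale (adjusted p = 0.0122) and lost the call without TG Sham replicate 3 (adjusted p = 0.055). Phlda1 fell by 1.24 ± 0.21 (adjusted p = 0.00131), Adcy1, an adenylyl cyclase, by 1.08 ± 0.22 (adjusted p = 0.00616) and Pde1c, a calmodulin-dependent phosphodiesterase, by 0.62 ± 0.08 (adjusted p = 5.16e-06). The hypertrophy and matrix genes had no call: Nppa was at -1.59 ± 0.72 (adjusted p = 0.632), Col1a1 at 0.10 ± 0.42 (adjusted p = 0.998) and Postn at -0.03 ± 0.71 (adjusted p = 0.998). Nppa ran from 48.8 to 177 CPM in TG Sham and from 239 to 461 CPM in NTG Sham hearts, without overlap. The standard errors use a spread shared by all groups, including the widely spread NTG TAC hearts. Postn ran from 33 to 51.8 CPM in NTG Sham and from 36.4 to 47.6 CPM in TG Sham hearts. The 23 macrophage markers had 0 calls (0 adjusted over the list alone) but 23 positive values, and camera called the list up (adjusted p = 3.72e-06, and adjusted p = 0.534 with an estimated correlation). In all, 81 genes were higher and 18 lower in TG Sham hearts (n = 5 and 5). The count of 99 was 56 without TG Sham replicate 1, 65 without NTG Sham replicate 4 and 247 in a fit of these 10 libraries alone.

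**Figure D2:**
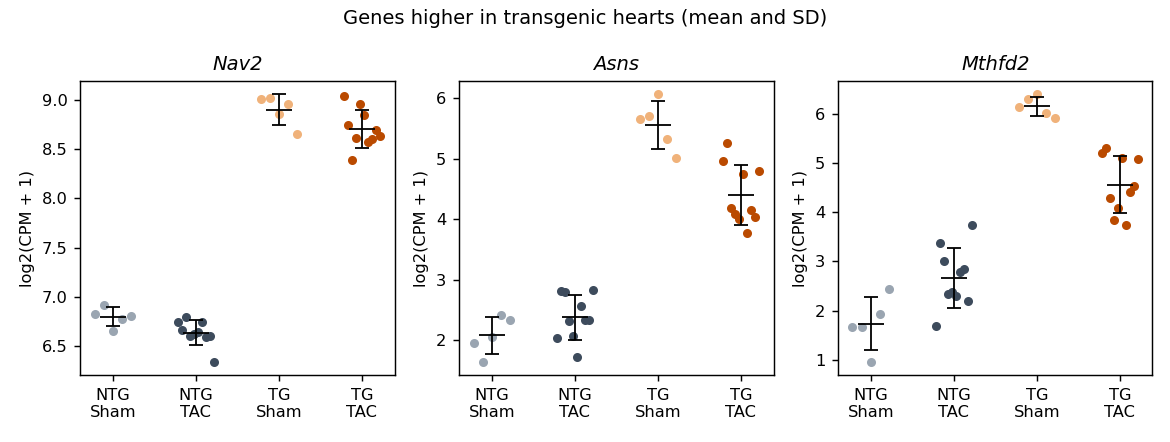
Log2(CPM + 1) of Nav2, Asns and Mthfd2 in each heart by group (points), with the mean and SD (black). All TG hearts lie above all NTG hearts for Nav2.

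The fourth comparison asks how the 2 genotypes differ after TAC. Genes of the hypertrophy programme and the matrix were on average lower in TG TAC than in NTG TAC hearts. Nppa was lower by a log2 fold change of -2.98 ± 0.53 (adjusted p = 0.000991, edgeR, n = 10 and 10), at 561 ± 277 against 4419 ± 3817 CPM (SD), and lay below the NTG TAC mean in 10 of 10 hearts. NTG TAC hearts ran from 386 to 9462 CPM and 5 of the 10 also lay below that mean, while TG TAC hearts ran from 87.8 to 994 CPM. Myh7 was at -1.28 ± 0.27 (adjusted p = 0.00416) and Nmrk2, a nicotinamide riboside kinase, at -4.02 ± 0.74 (adjusted p = 0.00162). Nppb was at -1.32 ± 0.35 (adjusted p = 0.0184) and lost the call without NTG TAC replicate 2 (adjusted p = 0.0502). Acta1 did not differ past the threshold, at -0.33 ± 0.36 (adjusted p = 0.579). NTG TAC replicates 1, 4, 6, 7 and 9 lay below the highest TG TAC heart for Postn, Col1a1 and Nppb. Their highest values were 123, 272 and 401 CPM, against 137, 278 and 413 CPM in TG TAC hearts. The other NTG TAC hearts lay above all TG TAC hearts for these genes. The labels give no pressure gradient, so whether constriction differed between the genotypes was not tested.

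Of the 17 hypertrophy genes, 11 were lower and 0 higher (14 and 1 adjusted over the list alone). Of the 34 matrix genes, 28 were lower and 0 higher (33 and 0 adjusted over the list alone), such as Col12a1, a fibril-associated collagen, at -2.95 ± 0.56 (adjusted p = 0.00197), Comp, a cartilage matrix protein, at -2.88 ± 0.59 (adjusted p = 0.00357), Postn at -2.28 ± 0.50 (adjusted p = 0.00632) and Lox, a collagen cross-linking enzyme, at -2.70 ± 0.56 (adjusted p = 0.00424). Col1a1 was at -1.10 ± 0.30 (adjusted p = 0.0201), and without NTG TAC replicate 10 it was at -0.79 (adjusted p = 0.0606). Spp1, which encodes osteopontin, was at -3.68 ± 0.88 (adjusted p = 0.0106), and without the same library at -1.64 (adjusted p = 0.0646). In the transforming growth factor beta list, 8 of 20 members were lower (13 adjusted over the list alone). Camera called these 3 lists down (adjusted p = 7.15e-06, 2.01e-12 and 1.38e-05), with adjusted p = 0.549, 0.534 and 0.507 with an estimated correlation. With 1 surrogate variable Postn was at -0.40 (adjusted p = 0.447), Lox at -0.47 (0.126), Comp at -0.87 (0.261), Myh7 at -0.41 (0.124) and Nmrk2 at -0.99 (0.281), and Spp1 turned to 0.36 (0.764). Col1a1 was at -0.07 (0.785) and Nppb at -0.38 (0.506). With voom weights Col1a1 was at -0.48 (0.216), Nppb at -0.77 (0.156) and Spp1 at -0.98 (0.337), and Postn, Lox, Comp, Col12a1 and Nmrk2 did not pass either (adjusted p = 0.145, 0.118, 0.134, 0.0739 and 0.0953). With limma-trend, Postn, Lox, Comp, Col1a1, Spp1 and Nppb did not pass (0.0758, 0.0507, 0.0515, 0.108, 0.153 and 0.0515).

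The 5 largest rises in TG TAC hearts were in Asns, Cacng6, Nav2, Mthfd2 and Aldh1l2. Nav2 was at a log2 fold change of 2.09 ± 0.07 (adjusted p = 1.34e-20), Asns at 2.26 ± 0.21 (adjusted p = 3.7e-08), Mthfd2 at 2.01 ± 0.26 (adjusted p = 1.37e-05) and Aldh1l2 at 1.76 ± 0.21 (adjusted p = 1.75e-06). Cacng6, a calcium channel subunit, was at 2.13 ± 0.30 (adjusted p = 4.48e-05). In the unfolded protein and integrated stress response list, 10 of 23 members were higher (15 adjusted over the list alone), among them the endoplasmic reticulum chaperones Hspa5 at 0.45 ± 0.08 (adjusted p = 0.000346) and Dnajb9 at 0.73 ± 0.10 (adjusted p = 1.51e-05). Camera called the list up (adjusted p = 1.12e-09, and adjusted p = 0.507 with an estimated correlation). The oxidative phosphorylation list had 48 positive values of 50, 0 calls (0 adjusted over the list alone) and a median log2 fold change of 0.09, and camera called it up (adjusted p = 3.15e-05, and adjusted p = 0.707 with an estimated correlation). Acta2, the smooth muscle form of alpha-actin, was higher at 0.89 ± 0.13 (adjusted p = 9.01e-05). Cell cycle genes were lower in 4 of 19 cases (10 adjusted over the list alone), such as Mcm2, a replication licensing factor, at -0.62 ± 0.12 (adjusted p = 0.00223), and camera called the list down (adjusted p = 0.00202, and adjusted p = 0.58 with an estimated correlation).

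**Figure D3:**
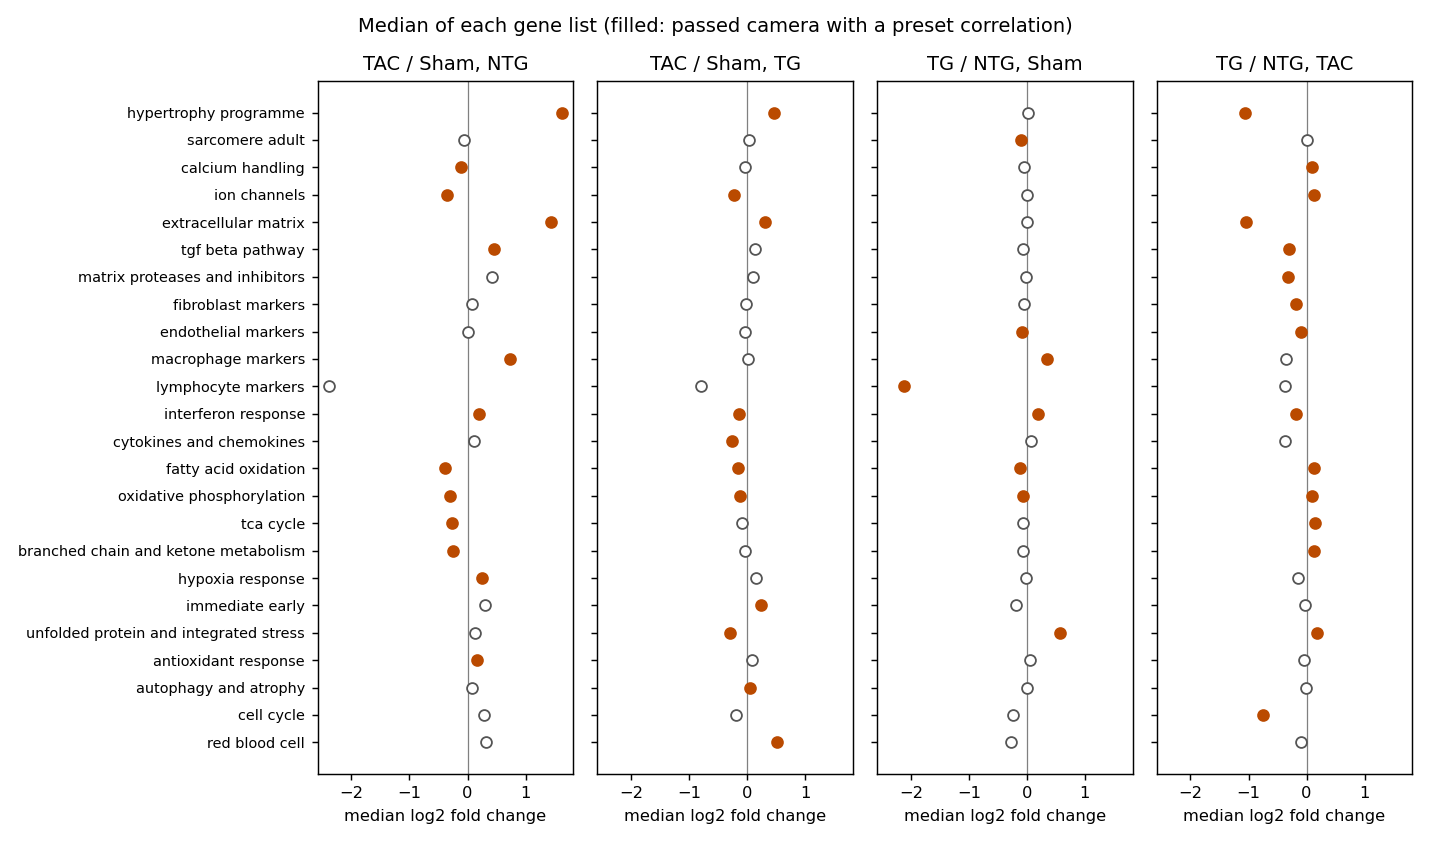
Median log2 fold change of the gene lists that passed camera in at least 1 comparison (y axis), in 4 comparisons (panels). Filled points passed with a preset correlation of 0.01, such as the hypertrophy list at 1.63 in NTG hearts and 0.47 in TG hearts (both adjusted p = 0.507 with an estimated correlation, with which 1 of 165 tests passed).

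In all, 621 genes were higher and 932 lower in TG TAC hearts. The count of 1553 was 2384 without NTG TAC replicate 1, 901 without replicate 2, 930 without replicate 3, 822 without replicate 10 and 980 without TG TAC replicate 1, and 600 in a fit of these 20 libraries alone. The mean root mean square deviation of log2 CPM from the group mean was 0.366 ± 0.089 (SD, n = 10) in NTG TAC and 0.256 ± 0.022 (SD, n = 10) in TG TAC libraries, a ratio of 1.43 (two-sided permutation test, p = 0.00032). Among the libraries with numbers under 100 the ratio was 1.36 (7 and 9 libraries, exact permutation test, p = 0.00114). The main model assumes 1 spread per gene for all groups, so this difference affects its standard errors and p-values in every comparison.

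The fifth comparison asks whether the TAC response differs between the genotypes. The edgeR quasi-likelihood test called 0 of 13588 genes, with 1103 at an unadjusted p under 0.05. DESeq2 called 5, among them Mthfd2, Gdf15 and Asns (adjusted p = 0.000211, 0.0157 and 0.0268), and limma-trend 1, Mthfd2 (0.0172). Mthfd2 came nearest, at an interaction log2 fold change of -2.78 ± 0.49 (adjusted p = 0.059). It passed without NTG Sham replicate 5, NTG TAC replicate 1 or 9, or TG TAC replicate 1 or 2 (adjusted p = 0.0453, 0.0227, 0.0479, 0.0206 and 0.0305). By edgeR, Gdf15, a stress-induced cytokine, had -4.35 ± 1.09 (adjusted p = 0.37), Asns -1.58 ± 0.37 (adjusted p = 0.266), Postn -2.25 ± 0.86 (adjusted p = 0.614) and Myh7 -1.32 ± 0.46 (adjusted p = 0.614). Nppa, lower in TG hearts already after Sham though not called there, had -1.39 (adjusted p = 0.64). Thus the separate calls of Nppb, Myh7, Col1a1 and Postn in NTG hearts alone are not shown to differ from TG hearts gene by gene. Camera called 15 lists, with the matrix list down by a median of -1.12 (adjusted p = 1.18e-09) and the unfolded protein and integrated stress list down by -0.41 (adjusted p = 6.58e-12). They had 0 called members each (0 and 10 adjusted over the list alone), and with an estimated correlation adjusted p = 0.549 and 0.507.

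Whether genes that change with TAC lie nearer to Sham levels in TG hearts was tested with separate NTG TAC libraries for the list and for the direction. The planned list, from the odd-numbered NTG TAC replicates, held 0 genes by the edgeR quasi-likelihood test, with 2064 at an unadjusted p under 0.05. With the even-numbered replicates it held 907 genes, of which 902 could be compared, and 715 (79.3%) went the opposite way in TG TAC against the odd-numbered NTG TAC hearts. Of 100 splits of those 15 TAC libraries, 34 gave a share as large, the real one included.

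Across the 10 NTG TAC hearts, Nppb and the mean of the matrix list rose together, with Pearson's r = 0.92 (permutation p = 0.00066, Benjamini-Hochberg adjusted 0.00132 over 2 relations) and Spearman's rho = 0.78 (permutation p = 0.0109, adjusted 0.0219). Without the 2 hearts farthest from the median of Nppb, r was 0.94 (exact permutation p = 0.00303) and rho 0.67 (exact permutation p = 0.0831, adjusted 0.166), and among the 7 hearts with numbers under 100 r was 0.94 (exact permutation p = 0.00714) and rho 0.64 (exact permutation p = 0.139, adjusted 0.278). The rank relation thus did not pass in either. NTG TAC replicates 1, 4, 6, 7 and 9 had 8.08 to 8.65 for Nppb and 4.96 to 5.83 for the matrix mean (log2). The others had 9.25 to 10.77 and 6.78 to 8.12. Both subsets above kept hearts of each set, so r includes the gap between the sets. The relation within each set was not tested. Across the 10 TG TAC hearts, r was 0.56 (permutation p = 0.0845, adjusted 0.0845) and rho 0.50 (permutation p = 0.143, adjusted 0.143). Without the 2 farthest hearts r was -0.06 (exact permutation p = 0.895), and among the 9 with numbers under 100 it was 0.29 (exact permutation p = 0.445). The difference between the 2 relations was not tested.

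**Figure D4:**
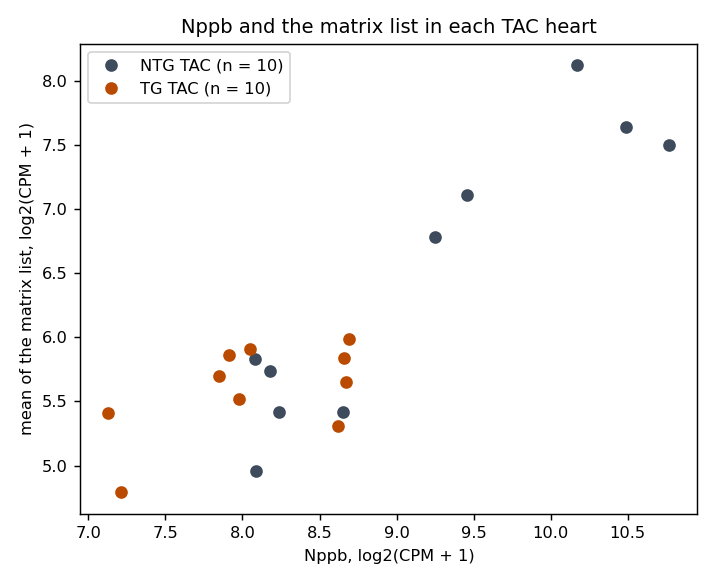
Mean log2(CPM + 1) of the matrix list (y axis) against log2(CPM + 1) of Nppb (x axis) in each TAC heart. The 10 NTG TAC hearts (r = 0.92) lie in a low and a high set, with matrix means of 4.96 to 5.83 and of 6.78 to 8.12.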

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

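All the tests of explanations and of other splits in this part were chosen after the results they weigh had been seen. A sample is named below as the lowest or highest of its own group where its gap to the nearest sample of its group is a large part of the group's range. Chance gives this in about 1 of 20 groups, so 7.4 of 148 groups, and 17 were seen.

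In depth and composition, TG Sham replicate 5 had the lowest total of the TG Sham libraries (9.349 in units of 1e6 counts), and NTG TAC replicate 10 had the lowest share of counts on its 10 highest genes (9.46%) and the highest TMM factor (1.072) of the NTG TAC libraries. The other values are mean scores of gene lists, each lowest or highest within its own group. NTG TAC replicate 10 was lowest for adult sarcomere genes (-0.345) and calcium-handling genes (-0.397) and highest for cytokines and chemokines (0.873). NTG TAC replicate 2 was highest for glycolysis (0.276) and hypoxia genes (0.958). TG TAC replicate 1 was lowest for hypertrophy genes (-0.657) and highest for ion channel genes (0.227), and TG TAC replicate 2 lowest for adipocyte markers (-0.842). Among the Sham hearts, NTG Sham replicate 5 was highest for cell cycle genes (1.062), TG Sham replicate 5 highest for antioxidant genes (0.066), TG Sham replicate 4 lowest for fibroblast markers (-0.221), TG Sham replicate 2 lowest for red blood cell genes (-0.842), NTG Sham replicate 4 lowest for neutrophil and mast cell markers (0.013) and NTG Sham replicate 1 lowest for mesothelial and nerve markers (-0.159).

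The TAC response differed between the genotypes in 15 gene lists by an interaction test with a preset correlation (camera), and in 0 of them with an estimated correlation, where adjusted p ran from 0.507 to 0.655. Fry called 1 of 33 lists for the interaction. The median interaction log2 fold change was -1.12 for the matrix (adjusted p = 1.18e-09), -0.84 for hypertrophy (0.000697), -0.74 for macrophage markers (1.35e-07), -0.58 for cytokines (0.0167), -0.42 for interferon response (1e-07), -0.41 for the unfolded protein and integrated stress response (6.58e-12), -0.40 for the cell cycle (0.00265) and -0.33 for the transforming growth factor beta pathway (0.00595). It was 0.24 for fatty acid oxidation (1.22e-06), 0.22 for branched-chain and ketone metabolism (2.55e-08), 0.20 for the tricarboxylic acid cycle (1.06e-07), 0.18 for mural markers (0.0354), 0.16 for oxidative phosphorylation (1.51e-09), 0.16 for calcium handling (0.00258) and 0.11 for adult sarcomere genes (0.015).

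Lymphocyte genes were high in 1 library, NTG Sham replicate 5. Thymus tissue in this library is a candidate explanation: 7 thymic epithelium genes summed to 783 counts there and to at most 12 elsewhere, and 8 thymocyte genes to 1883 against at most 565. All 7 thymic epithelium genes and 7 of the 8 thymocyte genes were highest in this library. Blood lymphocytes are argued against, since B lymphocyte genes lay at 0.908 times the mean of the other libraries. The count of Xist, 202 against at most 13 elsewhere, goes with RNA of a female mouse, while the Y-linked counts, 1400, lay within the range of the others (1037 to 1985). Without NTG Sham replicate 5, 1851 genes were called for TAC in NTG hearts, in place of 2390. No further explanation was tested.

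Nav2 was higher in TG hearts after Sham and after TAC, at a log2 fold change from 2.04 to 2.17 over the alternatives. A gain in copy number of the whole region is argued against, since the 8 genes tested within 2 Mb had a median of 0.00 and a largest absolute change of 0.88, below that of Nav2. After TAC 2 of them were called in opposite directions, Ano5 (0.88, adjusted p = 0.0315) and Csrp3 (-0.37, adjusted p = 0.0106), and a strain difference in the region was not tested. A difference in library scaling is argued against, since the TMM factors ran only from 0.961 (NTG TAC replicate 2) to 1.072 (NTG TAC replicate 10). With RLE factors, upper-quartile factors or library totals alone Nav2 was no lower than 2.07. Scalings so close to each other could hardly move it, so that value adds no support. A transgene inserted at Nav2 may be a source, and cannot be told apart from a response to the receptor: counts per gene hold no positions, and the interaction of Nav2, -0.03 ± 0.12, does not decide between them.

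TG TAC replicate 1 lay at 0.30 between the Sham and TAC means over all genes, where the highest TG Sham heart lay at 0.32, and over the genes called without it at 0.31, where the TG Sham hearts lay between -0.15 and 0.24 (mean 0.07 ± 0.16, SD, n = 5). Its Acta1 (1236 CPM, against 271 to 687) and Mthfd2 (35.9 CPM, against 59.1 to 83.1), genes chosen after their values were seen, lay outside the TG Sham range on the side of TAC. NTG Sham hearts ran from 551 to 1302 CPM for Acta1, so its Acta1 was within the range of that Sham group. A swap with an NTG heart is argued against, since its Nav2 was 524 CPM and the highest NTG heart had 120 CPM. A Sham heart under a TAC label and a weak constriction cannot be told apart: 0.31 is too near the spread of the Sham hearts to decide, and 0 columns of the labels give a pressure gradient. No other biological explanation was tested.

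Other splits of the libraries, 100 for each count with the real one included, gave as many called genes in 4 for TAC in NTG hearts (2390, highest other 3868) and in 2 for genotype after TAC (1553, highest other 1909). For TAC in TG hearts (194, highest other 11) and genotype after Sham (99, highest other 8) only 1 did, the real one. For each of these 4 counts the share was under 1 in 20. For TAC in NTG hearts, 4 of 100 splits is too near that mark to exclude chance. For this count and for genotype after TAC, some splits called more genes than the real one. What sets those splits apart was not tested. For the interaction the splits decide nothing, since the real count is 0 and any split gives as many (100 of 100, highest other 47). For the share of TAC genes nearer to Sham levels in TG hearts, chance is not excluded: 34 gave a share as large as 79.3% (highest other 98.0%), and with a spread shared over all libraries and the odd-numbered list, 20 gave one as large as 84.6% (highest other 91.6%).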

How the results depend on the processing

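Leaving out the library with lymphocyte transcripts, the gene lists without each library, the overlap in fits of the groups alone, the shared spread and the relation among numbers under 100 were chosen after seeing the data, and the other alternatives were planned. A sex term was not run, since every library holds Y-linked counts. Where a result changed, the cause was not tested.

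TAC in NTG hearts (2390 genes) gave 218 in a fit of its groups alone, 316 with 1 surrogate variable and 372 against a fold of 1.2. TAC in TG hearts (194) gave 381 with DESeq2, 1305 with voom, 954 with its groups alone, 15 with the sample-number term, 794 with 1 surrogate variable and 34 against a fold of 1.2. Genotype after Sham (99) gave 248 with voom, 247 with its groups alone, 183 with 1 surrogate variable and 25 against a fold of 1.2. Genotype after TAC (1553) gave 621, 600, 337 and 89 in the same order. The interaction (0) gave 5 with DESeq2, 1 with limma-trend and 1 without the library with lymphocyte transcripts. Leaving out 1 library at a time gave 1550 to 3200, 93 to 296, 56 to 115, 822 to 2384 and 0 to 2 genes for the 5 comparisons. With the replicate number as a block, 955 genes rose and 866 fell with TAC in NTG hearts.

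Of 165 list tests, 62 passed camera with the preset correlation, 1 with an estimated correlation and 19 by fry, and 57 to 65 without 1 library. Fry called 11 lists for TAC in NTG hearts and 5 for genotype after TAC. For TAC in TG hearts, genotype after Sham and the interaction it called 1 each. The overlap of TAC calls (125) was 229 with DESeq2 and 41 at adjusted p under 0.01. The planned list of TAC genes nearer to Sham levels held 0 genes, as it did at adjusted p under 0.01, with RLE factors and without the library with lymphocyte transcripts. It gave 715 such genes with the even-numbered list, and 121 (odd) and 2533 (even) with a spread shared over all libraries. The Nppb and matrix relation in TG TAC hearts fell to r = -0.06 without the 2 farthest hearts.

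These results, each a call in at least 1 of the 2 settings, turned direction. The macrophage list for TAC in TG hearts had adjusted p = 0.003005, down, with the sample-number term. The lymphocyte list for genotype after Sham had adjusted p = 0.9832, up, without NTG Sham replicate 5, the library with lymphocyte transcripts, and 0.007036 without NTG Sham replicate 3. Without NTG Sham replicate 5, Cd8a (0.099) and Lck (0.236) turned for TAC in NTG hearts, and were at -4.374 and -3.614 without NTG TAC replicate 1. With 1 surrogate variable, Lgals3 turned for TAC in NTG hearts (-0.034), and Lgals3 (0.015), Col3a1 (0.012) and Spp1 (0.361) turned for genotype after TAC. Among values that passed in neither setting, signs changed for Nppa in the interaction (0.348) and Acta1 for genotype after TAC (0.119) with 1 surrogate variable, for Cd8b1 for genotype after Sham without NTG Sham replicate 5 (0.534), and for Col3a1, Col1a1, Postn and the Nav2 interaction at values between -0.049 and 0.041.

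Of 147 results for single genes in the 5 comparisons (90 different genes), 119 were calls. Of these, 97 passed without each single library and 34 under every other setting chosen in advance. Totals of 9231678 to 13093351 counts leave genes under about 0.3 CPM with 3 counts or fewer.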

Other observations

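The genotype calls after Sham and after TAC shared 63 higher and 13 lower genes, where 3.70 and 1.23 would be shared by chance if the sets were unrelated, and 0 genes were called in opposite directions by edgeR. Both sets use the same spread per gene from 1 fit, which these chance values do not allow for. Of the 99 genes called after Sham, 96 had the same sign after TAC. Over all genes the 2 genotype changes had Pearson's r = 0.23.

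The sex check found counts of Y-linked genes in each of the 30 libraries.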
